A study of Mus musculus with 6 samples.

How the data were processed

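Poly(A)-enriched RNA from the mouse hepatocyte line AML12 was sequenced in 6 samples, 3 of untreated cells (Control 2, 3 and 4) and 3 of cells exposed to a static magnetic field (SMF 1, 2 and 3). Per the labels, RNA was extracted with TRIZOL, mRNA was captured on oligo(dT) beads, and libraries were made with the VAHTS Universal V6 kit from random-primed cDNA. No strand marking is stated, so reads of a gene and of an overlapping or antisense gene cannot be told apart. Group and replicate number were taken from the sample titles.

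The deposited files give FPKM (fragments scaled to gene length and library total), calculated by the authors, 1 file per library, for 23886 Ensembl gene identifiers. Per the submitters' processing notes, the genome build was GRCm39 and the tools were HISAT2 2.1.0 and Bowtie2 2.2.3, with no role or order stated. The counting tool, the annotation release and the treatment of reads that map to several places are not given in the sources used here. Genes with near-identical copies, such as ribosomal protein genes with processed pseudogenes and class I histocompatibility genes, are therefore uncertain. Symbols came from a GENCODE M21 gene table, which named 23521 of the 23886 identifiers. That annotation is on build GRCm38, so it served for symbols, GC content and length, and no coordinates are given.

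The FPKM of a gene proved to be whole multiples of 1 read divided by gene length and library total. For each of the 22004 genes above 0 in at least 1 library, 100% of values came out whole within a tolerance of 0.02 reads. The step of each gene was searched for so that its values came out whole, which a gene seen in 1 library meets whatever its value. Where the M21 exon length was a whole multiple of a recovered length and reads were few, reads and length were raised to that multiple. After this step the gene lengths equalled the M21 exon length for 97.59% of 21741 genes, a share that is therefore not independent of the annotation. Library totals behind the FPKM were 16601816, 18200516 and 17031387 reads for Control 2, 3 and 4, and 15514530, 17279772 and 17969397 reads for SMF 1, 2 and 3. Between 99.69% and 99.7% of each total lay in the listed genes. In a gene of 1 kilobase, 1 read was worth 0.0549 to 0.0645 FPKM.

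The comparison of SMF with control libraries used limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a variance trend and no further scaling. Genes with an FPKM of at least 1 in at least 3 of the 6 libraries were tested (11114 genes), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Gene lists, 40 in all, were fixed before the data were examined, as were the tests, the alternatives and the rule for named genes. Of these, 36 had at least 5 tested members and entered camera with a preset inter-gene correlation of 0.01, beside camera with an estimated correlation and fry, each two-sided. A further test, limma-voom on the recovered reads of the same genes, was chosen after seeing the data, as was a GC content and length correction of its values.

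The named genes were, in each direction, the 10 with the largest fold past the threshold, or where fewer passed, the smallest unadjusted p. Each had a symbol other than a predicted or clone name, a mean of at least 2 FPKM in the higher group, and no overlap between the groups. From each list, up to 4 passing members were named, or otherwise the 2 with the highest mean FPKM. The calcium entry channel with the highest FPKM, Ppargc1a, Alb, Cry1 and Cry2 were named whatever they did. Members that passed only when adjusted over the list alone were named where 5 or fewer did, a choice made after their values were seen.

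Alternatives covered pseudocounts of 0.1 and 5, no filter and a filter at 5 FPKM, rescaling to TPM, median-of-ratios scaling, quantile normalization, no variance trend, a stricter threshold of 0.01, a minimum fold of 1.5, and leaving out each library. A block on replicate number and a correction within each library for a smooth trend in GC content and gene length (loess, span 0.3) were also run. The correction used the 99.47% of tested genes that had both properties. For a description of the called lists, their medians were ranked among 10000 random lists matched on GC content, length and mean level. Genes of the random lists were drawn independently from outside the tested lists, so real members that vary together can rank at an extreme. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

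Both tests were tested on simulated data of 11136 genes with 200 changed genes. limma on log2(FPKM + 1) recovered 40% of genes changed 1.2-fold, 94% at 1.5-fold and 100% at 2-fold and 3-fold, with 11 false calls among 180. limma-voom recovered 74%, 98%, 100% and 100%, with 31 false calls among 225. A list shifted by 0.15 on the log2 scale was called by camera (adjusted p = 1.05e-20), with 1 further list that shares members with it. Genes were simulated independently, with 1 dispersion and no trend in GC content or length. The simulation therefore cannot show how camera with the preset correlation behaves on real lists whose members vary together. In pairs of libraries of 1 group, reads differed by more than sampling noise, with a chi-square of 3.32 to 6.3 per gene, so each library counted as 1 replicate. Pairs from different groups ran from 3.672 (Control 3 and SMF 2) to 11.953 (Control 4 and SMF 1), so the ranges overlapped. No label says that samples of a group came from separate cultures. The p-values other than those of camera therefore measure only the spread between these samples, which may be technical. Those of camera compare list members with other genes, and the preset correlation takes the members as nearly independent.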

Results

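Gene expression was measured by poly(A) RNA sequencing in AML12 cells, a hepatocyte line established from mouse liver. Of the 6 libraries, 3 came from untreated cells (Control 2, 3 and 4) and 3 from cells exposed to a static magnetic field, a field that does not vary with time (SMF 1, 2 and 3). Field strength and exposure time are not given in the sources used here. The title of the series names liver injury, calcium entry and cellular respiration, so the comparison asks which transcripts, and which genes of those functions, differ between exposed and untreated hepatocytes. Library totals ran from 15514530 reads in SMF 1 to 18200516 in Control 3, and the totals of the groups overlapped. Across the 11114 genes tested, the Pearson correlation of log2(FPKM + 1) was 0.9911 to 0.9927 between libraries of 1 group and 0.9865 to 0.9915 between groups; genes are not independent replicates. The first principal component held 34.4% of the variance and separated the groups, with controls at -12.96 to -3.37 and SMF libraries at 5.11 to 12.91.

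As groups, tested by camera with a preset inter-gene correlation, the lists of nuclear-encoded respiratory chain subunits and of cytoplasmic ribosomal proteins rose in the SMF libraries, with no single member passing limma over all genes. Their members differed by a median of 0.11 to 0.14 on the log2(FPKM + 1) scale, the scale of fold changes here except where limma-voom, reads or a plain FPKM ratio are named. The log2 fold of a gene after the GC content and length correction is also on the log2(FPKM + 1) scale. A limma-voom adjusted p printed beside such a fold comes from a separate fit. Lists of ATF4 targets, autophagy and lysosome genes, NF-kB and inflammatory genes, and superoxide and peroxide removal also rose, by smaller or similar amounts. Lists of splicing and nuclear speckle genes, mitosis, hypoxia and HIF1 targets, and cholesterol synthesis fell. Of the 36 lists tested, 7 were higher and 4 lower by camera (6 higher and 6 lower after rescaling to TPM or quantile normalization). Under TPM the filter acted on the rescaled values, so 13131 genes were tested in place of 11114. None of the 11 calls held with an estimated inter-gene correlation, where adjusted p = 0.516 to 0.698, or with the directional test of fry, where adjusted p = 0.176 to 0.484. The estimated correlation was 0.529 for the ribosomal list, 0.304 for complex I and 0.339 for complexes II to V, against the preset 0.01. The mixed test of fry, which asks whether members changed in either direction, passed for 9 of the 11 (adjusted p = 0.0136 to 0.0449; not hypoxia, 0.445, or superoxide removal, 0.168) and for 15 of the 25 lists not called.

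**Figure D1:**
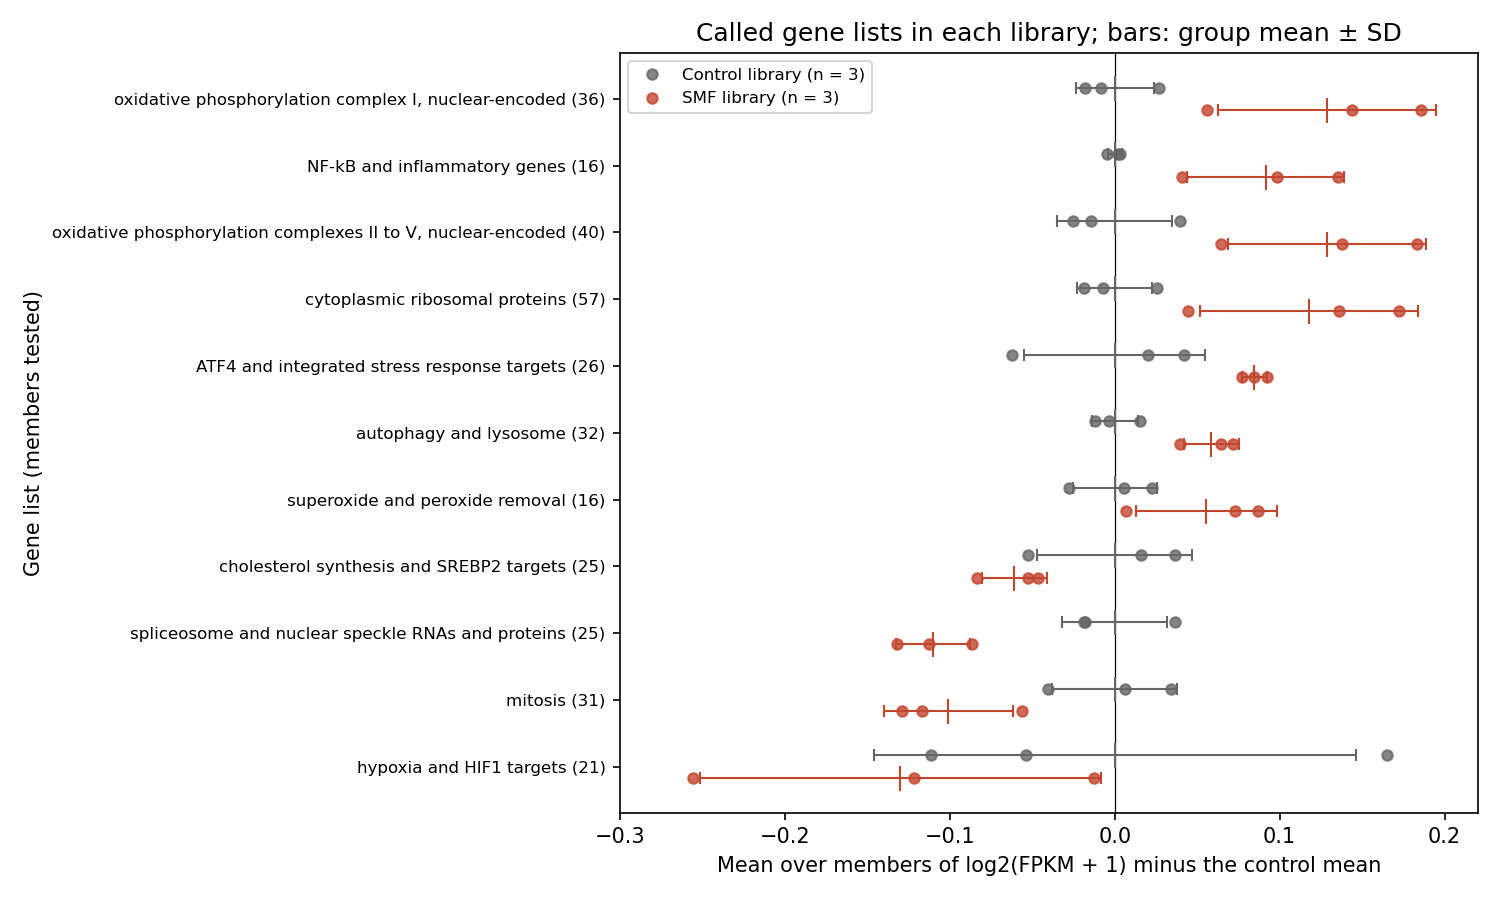
Mean over list members of log2(FPKM + 1) minus the control mean, per library, for the 11 called lists. Points are libraries (3 per group), bars are group means ± SD; for complex I the SMF libraries lie at 0.056 to 0.19 and the controls at -0.018 to 0.027.

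Complex I, the entry point of electrons from NADH into the respiratory chain, had 36 measured nuclear-encoded subunits, of which 31 had a fold above 0 (median 0.14, camera adjusted p = 6.341e-10). None of the 36 passed limma over all genes, and 14 passed adjusted over the list alone. Ndufa12 (ENSMUSG00000020022), an accessory subunit, was at 32.8 ± 1.57 FPKM in controls and 42.0 ± 1.9 in SMF libraries (SD, n = 3), a ratio of 1.28. Ndufa2 stood at 158.9 ± 11.3 and 192.0 ± 18.8 FPKM, and Ndufb11 at 127.8 ± 2.37 and 135.3 ± 10.3; the log2 fold of Ndufa2 went from 0.27 to 0.14 after the GC content and length correction (limma-voom adjusted p = 0.713). The list score of all 3 SMF libraries lay above every control, at 0.056 in SMF 2 and 0.14 and 0.19 in SMF 3 and SMF 1, against 0.027 in the highest control. This list has a median gene length of 1643.5 bases, and short genes were higher in SMF libraries in general. After correction within each library for GC content and length its median was 0.10 (camera adjusted p = 1.292e-05), and the score of SMF 2 then lay within the control range.

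Among the nuclear-encoded subunits of complexes II to V, 37 of 40 had a fold above 0 (median 0.12, camera adjusted p = 6.348e-11). None passed over all genes, and 16 passed adjusted over the list alone. Cox6b1 (ENSMUSG00000036751), a subunit of cytochrome c oxidase, measured 207 ± 4.93 FPKM in controls and 242.5 ± 7.6 in SMF libraries. Cox8a, another cytochrome c oxidase subunit, was at 593.4 ± 36.6 and 728.8 ± 65.9 FPKM, while Atp5a1, of the ATP synthase, was at 453.3 ± 14.2 and 467.5 ± 9.72. The log2 fold of Cox8a went from 0.29 to 0.16 after the GC content and length correction (limma-voom adjusted p = 0.241). The corrected median was 0.07 (camera adjusted p = 1.713e-08), with SMF 2 again within the control range.

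Among cytoplasmic ribosomal protein genes, 52 of 57 had a fold above 0 (median 0.11, camera adjusted p = 9.814e-14), and 8 passed adjusted over the list alone, with none over all genes. Rplp1, a protein of the ribosomal stalk, stood at 2661 ± 92.2 FPKM in controls and 3081 ± 218.6 in SMF libraries. Rplp0, its partner in the stalk, stood at 2093 ± 82.4 and 2290 ± 156.4. The log2 fold of Rplp1 went from 0.21 to 0.08 after the GC content and length correction (limma-voom adjusted p = 0.594), and that of Rplp0 from 0.13 to 0.03 (0.829). The corrected median was 0.07 (camera adjusted p = 1.713e-08), and SMF 2 then lay within the control range. Quantile normalization lowered the median to 0.046. Processed pseudogenes of ribosomal protein genes may take or give reads, since the treatment of reads that map to several places is not given in the sources used here.

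Transcripts encoded by mitochondrial DNA were not called as a list. Of 10 tested, 5 had a fold above 0 and 5 below (camera adjusted p = 0.944), and the difference from the nuclear-encoded lists was not tested. The most abundant, mt-Co1 and mt-Cytb, were at 5185 ± 307 and 3855 ± 170.8 FPKM in controls and 4627 ± 357 and 3848 ± 207.1 in SMF libraries. The first, mt-Co1, was lower by limma-voom (adjusted p = 0.0232) and not by limma on log2(FPKM + 1) (adjusted p = 0.246) or by limma-voom after the GC content and length correction (adjusted p = 0.0851). The log2 fold of mt-Co1 went from -0.17 to -0.12 under that correction. Mitochondrial genes took 1.995 ± 0.125% of reads in controls and 1.86 ± 0.0996% in SMF libraries (exact permutation p = 0.3, two-sided, where 0.1 is the smallest possible). The tricarboxylic acid cycle list, with 12 of 21 above 0 (adjusted p = 0.652), the mitochondrial biogenesis and dynamics list, with 10 of 22 (adjusted p = 0.994), and glycolysis, with 5 of 16 (adjusted p = 0.906), were not called. Glycolysis was called lower on limma-voom values after the GC content and length correction (median -0.051, adjusted p = 0.0313), though not by limma with that correction (median -0.046, adjusted p = 0.124). Its limma median turned above 0 without Control 2 or SMF 2, at 0.029 and 0.046 as deposited and 0.007 and 0.011 with the correction. Ppargc1a, a coactivator of mitochondrial biogenesis, fell below the filter at 0.70 ± 0.063 FPKM in controls and 0.61 ± 0.21 in SMF libraries and was not tested.

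None of the 3 calcium lists was called by camera. The mixed test of fry passed for calcium stores and for calmodulin, calcineurin and kinases (adjusted p = 0.0356 for each), and not for entry channels (0.168). Of 17 tested plasma membrane calcium entry channels and their regulators, 9 had a fold above 0 and 8 below (median 0.01, camera adjusted p = 0.931). None passed over all genes or adjusted over the list alone. The most abundant was Tmem63a, a channel opened by osmotic or mechanical stimuli, at 58.4 ± 3.25 FPKM in controls and 57.2 ± 0.26 in SMF libraries; Cacnb3, a subunit of voltage-gated channels, was at 52.4 ± 1.37 and 57.4 ± 1.76. For calcium stores, mitochondrial uptake and extrusion, 8 of 21 had a fold above 0 (adjusted p = 0.913), with Calr at 336 ± 12.01 and 359.1 ± 5.17 FPKM and Tmbim6 at 256.5 ± 2.46 and 274.4 ± 5.41. For calmodulin, calcineurin and calcium-dependent kinases, 5 of 17 had a fold above 0 (adjusted p = 0.717). Immediate early genes, many of them induced by calcium signals, were not called either, with 8 of 19 above 0 (adjusted p = 0.994); after the GC content and length correction the list was called lower, with a median of -0.07 (adjusted p = 0.0287), a call lost without Control 2 (median -0.062, adjusted p = 0.0672) or SMF 1 (median -0.036, adjusted p = 0.0856).

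Among stress and inflammatory genes, 20 of 26 ATF4 and integrated stress response targets had a fold above 0 (median 0.07, camera adjusted p = 0.000914). The 4 that passed adjusted over the list alone, named after their values were seen, were Cebpb, Gdf15, Sesn2 and Nupr1, while none passed over all genes. Cebpb, a transcription factor, was at 43.2 ± 3.33 FPKM in controls and 55.2 ± 3.01 in SMF libraries, and Gdf15, a secreted stress cytokine, at 6.999 ± 0.94 and 9.56 ± 0.27. After the GC content and length correction the log2 fold of Cebpb went from 0.35 to 0.17 and that of Sesn2 from 0.19 to 0.12, and neither passed limma-voom (adjusted p = 0.245 and 0.344). The abundant serine synthesis genes Phgdh and Psat1 were at 345.9 ± 13.0 and 237.8 ± 2.59 FPKM in controls and 369.0 ± 12.1 and 226.7 ± 7.11 in SMF libraries. The call was lost without Control 2 (median 0.028, adjusted p = 0.0564). After the GC content and length correction the median was 0.033 (adjusted p = 0.0287), and SMF libraries overlapped the controls. Among 10000 random lists matched on GC content, length and level, the uncorrected median lay at the 92.84 percentile, inside their middle 95% (0.0067 to 0.0786).

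In the NF-kB and inflammatory list, 12 of 16 genes had a fold above 0 (median 0.12, camera adjusted p = 0.00208), and Relb, Ccl20 and Csf1 passed adjusted over the list alone, the last pair named after their values were seen. Relb (ENSMUSG00000002983), an NF-kB subunit, stood at 11.4 ± 0.85 FPKM in controls and 14.96 ± 0.39 in SMF libraries. Ccl20, a chemokine, was at 22.4 ± 1.25 and 27.1 ± 1.56. Ccl2 and Cxcl5, the most abundant members, measured 297 ± 13.3 and 96.1 ± 3.34 FPKM in controls and 322.7 ± 4.43 and 101.5 ± 7.94 in SMF libraries. Without SMF 2 the list lost its call (median 0.13, adjusted p = 0.0647), as it did with no filter on low values. With the GC content and length correction the median was 0.11 (camera adjusted p = 3.035e-05), and every SMF library lay above every control. The corrected call, with the preset correlation, held with any 1 library left out.

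The autophagy and lysosome list had 25 of 32 genes above 0 (median 0.07, camera adjusted p = 0.0011), and its score was higher in 3 of 3 SMF libraries than in any control. That separation remained with the GC content and length correction (median 0.052, camera adjusted p = 0.0002625). Sqstm1, a selective autophagy receptor, at 179.1 ± 3.96 FPKM in controls and 199.4 ± 0.39 in SMF libraries, and Ctsb, a lysosomal protease, at 60.5 ± 1.26 and 66.5 ± 0.93, were higher adjusted over the list alone. Atg5, part of the autophagy conjugation machinery, was lower on the same count, at 18.5 ± 0.44 and 16.1 ± 0.24; Ctsb and Atg5 were named after their values were seen. Lamp1 was at 298.2 ± 5.57 and 312.2 ± 2.13 FPKM. Among genes for superoxide and peroxide removal, 14 of 16 were above 0 (median 0.06, camera adjusted p = 0.0271). Gpx4, which reduces lipid peroxides, measured 214.3 ± 8.73 FPKM in controls and 251.5 ± 16.6 in SMF libraries and was the 1 member that passed adjusted over the list alone; Txn1 was at 181.9 ± 3.5 and 186.5 ± 3.45. The log2 fold of Gpx4 went from 0.23 to 0.12 after the GC content and length correction (limma-voom adjusted p = 0.17). That list lost its call after the GC content and length correction (median 0.042, adjusted p = 0.177), under TPM and quantile scaling, with the replicate block (median 0.046, adjusted p = 0.166), and without Control 4 (median 0.053, adjusted p = 0.0976) or SMF 3 (median 0.046, adjusted p = 0.105). Its uncorrected median lay at the 83.67 percentile of matched lists.

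Of the lists that fell, splicing factors and nuclear speckle RNAs had 24 of 25 genes below 0 (median -0.10, camera adjusted p = 2.592e-06), with Neat1 and Son passing adjusted over the list alone. Neat1 (ENSMUSG00000092274), a long noncoding RNA of nuclear paraspeckles, was at 45.7 ± 1.45 FPKM in controls and 33.7 ± 3.62 in SMF libraries. Capture was on oligo(dT) beads, so this value need not cover forms of Neat1 without a poly(A) tail. Son, a speckle protein named after its values were seen, was at 16.1 ± 0.28 and 13.6 ± 0.65 (log2 fold -0.23, and -0.14 after the correction for GC content and length), and the abundant Hnrnpa1 and Hnrnpa2b1 were at 248.5 ± 5.91 and 231.1 ± 10.6 in controls and 230.3 ± 10.7 and 215.6 ± 4.33 in SMF libraries. These genes have a median length of 6983 bases, and the list lost its call after the GC content and length correction (median -0.012, adjusted p = 0.161). Mitosis genes had 29 of 31 below 0 (median -0.11, camera adjusted p = 2.592e-06), none passing singly adjusted over the list alone, and 3 of 3 SMF libraries lay below every control. Of its most abundant members, Plk1 was at 61.1 ± 1.46 and 61.4 ± 2.46 FPKM and Cks2 at 61.5 ± 0.81 and 60.7 ± 1.09. After the correction the mitosis median was -0.07 (adjusted p = 1.292e-05), with SMF 2 reaching into the control range.

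Hypoxia and HIF1 targets had 20 of 21 genes below 0 (median -0.14, camera adjusted p = 0.00593), none passing adjusted over the list alone. The libraries of both groups were widely spread and overlapped, with Control 2 at 0.17, Control 3 at -0.11 and Control 4 at -0.054, and SMF 1, 2 and 3 at -0.12, -0.26 and -0.013. The call was lost without Control 2 (median -0.063, adjusted p = 0.282) or SMF 2 (median -0.085, adjusted p = 0.342), and without SMF 3 the median was -0.21. The abundant glycolytic members Pgk1 and Ldha were at 556.9 ± 52.5 and 544.4 ± 38.2 FPKM in controls and 532.9 ± 36.9 and 542.2 ± 37.8 in SMF libraries. Cholesterol synthesis and SREBP2 targets had 17 of 25 below 0 (median -0.06, camera adjusted p = 0.0279). The scores of the groups overlapped, with Control 4 at -0.053 and SMF 1, 2 and 3 at -0.053, -0.047 and -0.084. The 4 that passed adjusted over the list alone were Sqle, squalene epoxidase, at 55.8 ± 0.74 FPKM in controls and 48.9 ± 0.53 in SMF libraries, and Msmo1, Acat2 and Cyp51, named after their values were seen. After the GC content and length correction the log2 fold of Msmo1 went from -0.17 to -0.09 and that of Cyp51 from -0.15 to -0.10. Ebp and Srebf2 were at 130.2 ± 1.38 and 99.2 ± 2.11 in controls and 138.4 ± 3.88 and 99.3 ± 0.48 in SMF libraries. This call was lost without Control 2 (median -0.017, adjusted p = 0.197), Control 3 (median -0.082, adjusted p = 0.15), SMF 2 (median -0.068, adjusted p = 0.0675) or SMF 3 (median -0.062, adjusted p = 0.0874), and without Control 4 the median was -0.11. It was also lost with no variance trend (adjusted p = 0.0568).

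Gene by gene, the differences were small. With limma on log2(FPKM + 1), 0 of 11114 genes passed in either direction (smallest adjusted p = 0.103), while 1998 had an unadjusted p below 0.05, 1046 higher and 952 lower, where chance would give 556. SMF libraries lay above every control for 1224 genes and below every control for 1407, together 23.7% of the genes, where chance gives 10%. Both chance figures are averages, and genes vary together, so a count away from them does not by itself show a group difference. Other groupings of the 6 libraries gave 241 to 1273 genes at an unadjusted p below 0.05. The share of separated genes was not counted in other groupings. limma-voom on recovered reads, chosen after seeing the data, called 238 genes higher and 259 lower, with a median absolute log2 fold of 0.24. That total of 497 depended on single libraries: it was 210 without Control 2, 450 without Control 3, 8 without Control 4, 59 without SMF 1, 1446 without SMF 2 and 77 without SMF 3. After the GC content and length correction limma-voom called 52 genes higher and 24 lower, among them 53 of the 497 in the same direction.

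The 20 genes named by rule were picked for a small p and full separation in these same libraries. Their passing limma-voom on the same reads therefore adds no independent support. In simulated data limma-voom gave 31 false calls among 225. None of the 20 passed limma on log2(FPKM + 1), and all 20 passed limma-voom, 9 of them also after the GC content and length correction. Under that correction the log2 fold shrank by over 1.5 times for Scand1 (0.30 to 0.09, limma-voom adjusted p = 0.796), Cox6b1 (0.23 to 0.10, 0.753), Bst2 (0.27 to 0.15, 0.336) and Ahnak (-0.18 to -0.10, 0.235), which lost their calls. Calls were also lost for H2-D1 (limma-voom adjusted p = 0.0503), Csrp1 (0.0992), Mrpl4 (0.109), Faap20 (0.224), Gcnt1 (0.0592), Sqle (0.052) and Snord71 (0.056). Those that also passed limma-voom with any 1 library left out and after the GC content and length correction were H2afj, Gstp1, Arrdc3 and Neat1, whose log2 folds went from 0.35 to 0.26, -0.56 to -0.65, -0.52 to -0.41 and -0.43 to -0.35 under the correction. Gstp1 (ENSMUSG00000060803), a glutathione S-transferase of the pi class, fell from 49.9 ± 3.0 to 33.7 ± 3.71 FPKM (limma-voom adjusted p = 5.64e-05). Arrdc3 (ENSMUSG00000074794), an arrestin-domain protein, fell from 3.28 ± 0.15 to 1.99 ± 0.12 FPKM, and H2afj (ENSMUSG00000060032), a histone H2A variant, rose from 100.1 ± 2.33 to 128.4 ± 10.9. The other higher genes by limma-voom, besides Ndufa12, Cox6b1 and Relb, were the class I histocompatibility gene H2-D1 (71.0 ± 1.45 to 82.8 ± 0.56 FPKM), the interferon-induced Bst2 (59.5 ± 1.62 to 71.7 ± 2.57), Csrp1 (53.5 ± 1.97 to 63.3 ± 0.67), the mitochondrial ribosomal protein gene Mrpl4 (23.6 ± 1.1 to 28.8 ± 0.41), Faap20 (9.78 ± 0.37 to 12.6 ± 0.64) and Scand1 (44.6 ± 2.79 to 55.0 ± 0.96). The other lower genes, besides Neat1 and Sqle, were Nedd1 (9.65 ± 0.35 to 7.4 ± 0.31 FPKM), the glycosyltransferase gene Gcnt1 (7.81 ± 0.41 to 6.06 ± 0.095), Kctd9 (5.06 ± 0.39 to 3.65 ± 0.15), Rrm2, a subunit of ribonucleotide reductase (73.9 ± 2.25 to 63.1 ± 2.47), and Ahnak (61.8 ± 1.47 to 54.3 ± 0.74). Snord71, a small nucleolar RNA, rested on a mean of 2.83 reads per library and was at 2.13, 4.53 and 4.14 FPKM in Control 2, 3 and 4 and 0, 0 and 0.655 in SMF 1, 2 and 3. Without Control 4, only Gstp1, Arrdc3, H2afj and Neat1 of the 20 passed limma-voom.

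**Figure D2:**
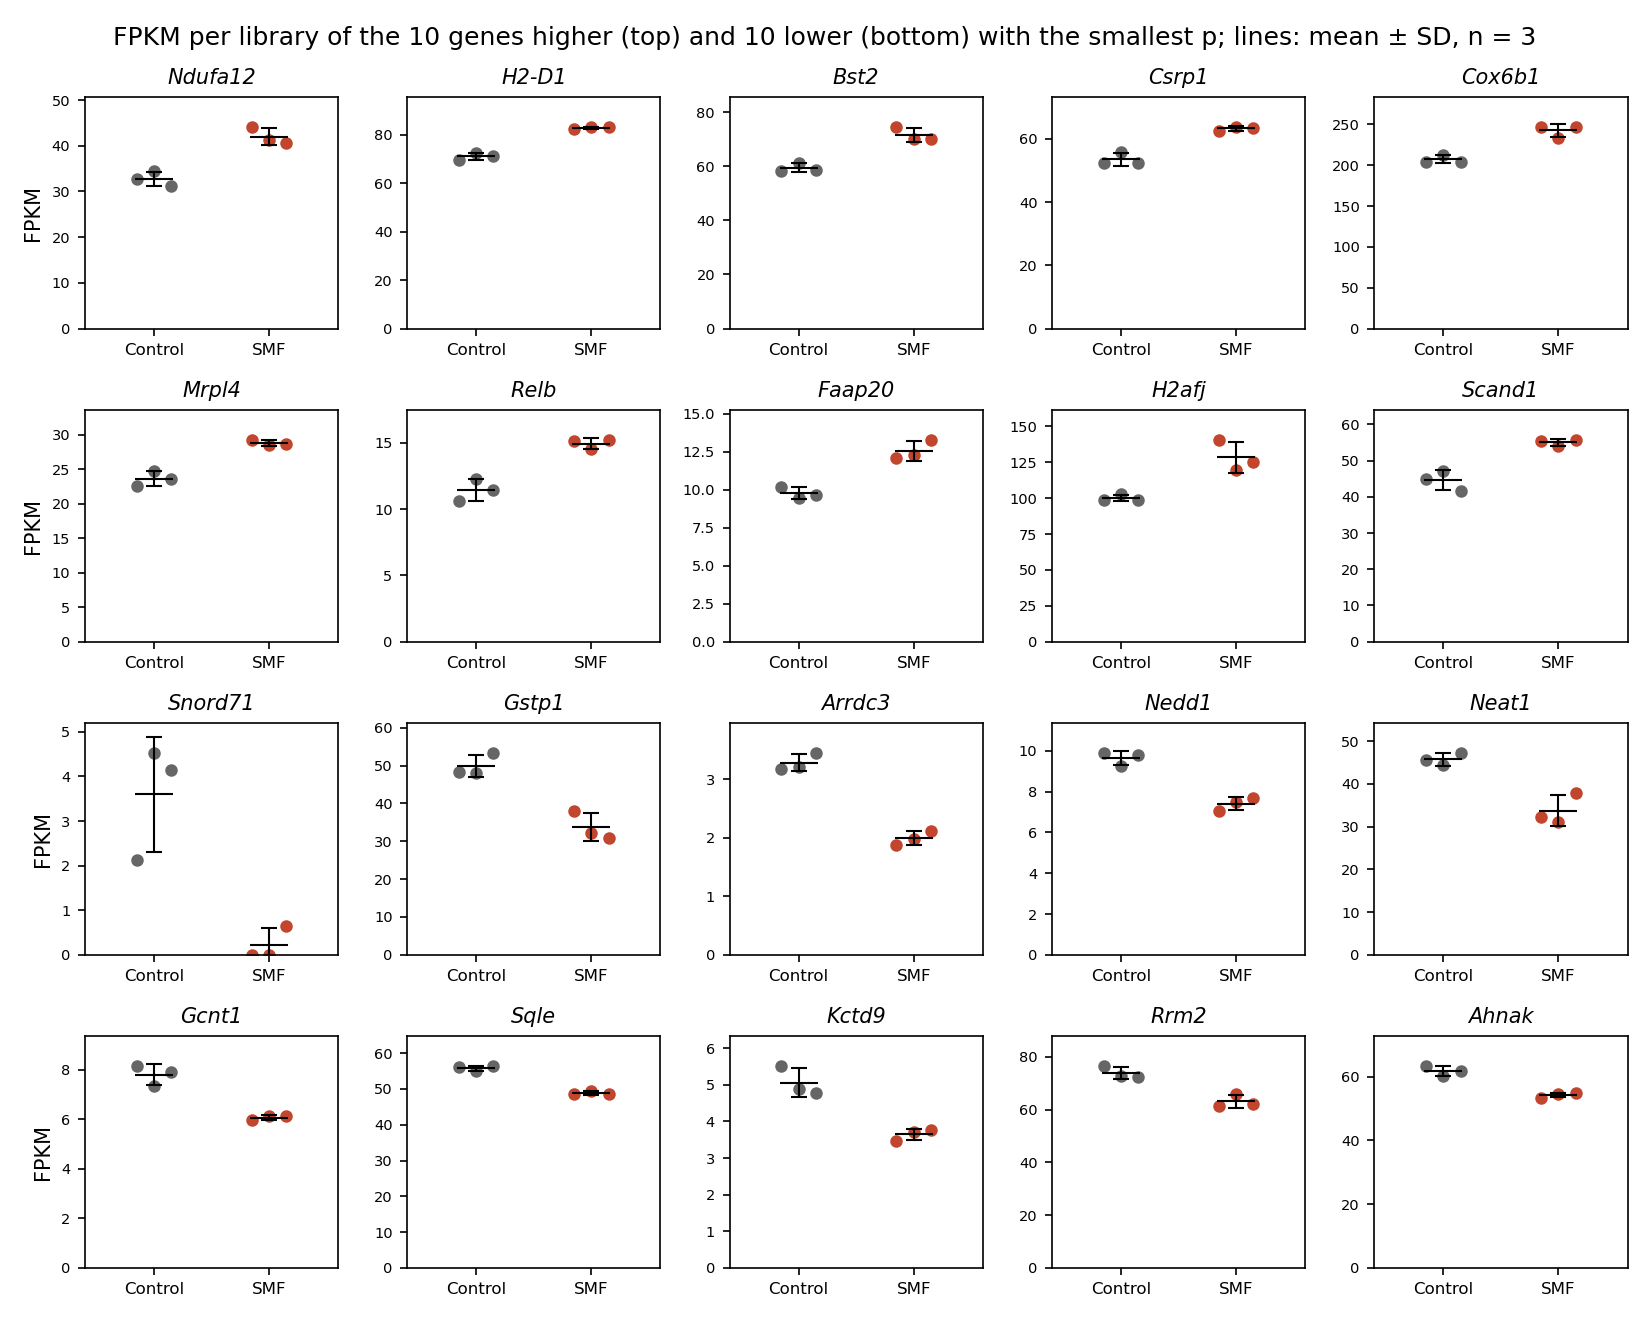
FPKM per library (vertical axes from 0) of the 10 genes higher and 10 lower in SMF libraries with the smallest p under the naming rule. Points are libraries, lines are mean ± SD (n = 3 per group); Gstp1 runs from 49.9 FPKM in controls to 33.7 in SMF libraries.

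Hepatocyte identity genes were not called. Among hepatocyte secreted proteins, 10 of 13 had a fold above 0 (camera adjusted p = 0.198), with Alb at 29.2 ± 4.33 FPKM in controls and 30.4 ± 2.8 in SMF libraries. Among hepatocyte metabolism and bile acid genes, 8 of 11 had a fold above 0 (camera adjusted p = 0.0723), with Hnf4a at 91.6 ± 4.32 and 91.4 ± 1.95 FPKM. Cholangiocyte and progenitor markers, with 8 of 11 above 0, were not called (camera adjusted p = 0.906), and Krt8, the most abundant member, was at 1921 ± 50.6 and 2018 ± 61.9 FPKM. After the GC content and length correction that list had a median of -0.030 and was still not called (camera adjusted p = 0.202). Its score in every SMF library then lay below every control. Of the markers of other cell types, 2 stellate or fibroblast, 3 macrophage or blood and 1 endothelial gene reached the filter, too few to test. The cryptochromes Cry1 and Cry2 were at 4.25 ± 0.71 and 3.65 ± 0.28 FPKM in controls and 3.87 ± 0.31 and 3.54 ± 0.39 in SMF libraries, and the circadian list, with 5 of 14 above 0, was not called (adjusted p = 0.931).

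The other fixed lists were not called. DNA replication had 11 of 36 genes above 0 (camera adjusted p = 0.0603), ribosome biogenesis 10 of 30 (0.121), fatty acid synthesis 6 of 19 (0.51), and TGF-beta targets and extracellular matrix 8 of 19 (0.51). Fatty acid oxidation and PPARA targets had 14 of 22 above 0 (0.0603), and the unfolded protein response 16 of 24 (0.168). Interferon response genes had 6 of 9 above 0 (0.595), iron handling 10 of 23 (0.652), NRF2 antioxidant targets 15 of 26 (0.666) and heat shock proteins 6 of 15 (0.907). YAP and TEAD targets had 9 of 19 above 0 (0.944), p53 targets 10 of 22 (0.994) and apoptosis regulators 10 of 19 (0.994). Single members of these lists passed adjusted over the list alone, while none passed limma over all genes; except for Rrm2, Bst2, Plin2 and Taldo1 they were named after their values were seen. Higher were Plin2 and Acot1 of fatty acid oxidation, Bst2 of the interferon list, the iron-sulfur scaffold gene Iscu (21.9 ± 1.25 FPKM in controls, 26.96 ± 1.55 in SMF libraries), Taldo1 of the NRF2 list, Hsf1, and Gadd45a of the YAP list (37.6 ± 0.88 and 44.7 ± 2.66). Lower were Rrm2 of DNA replication, the transferrin receptor gene Tfrc (34.2 ± 1.85 and 28.9 ± 1.59) and the chaperone genes Hsp90aa1 (82.4 ± 2.34 and 73.9 ± 3.05) and Hspa4l. After the GC content and length correction the log2 fold of Tfrc went from -0.24 to -0.12, that of Gadd45a from 0.24 to 0.14, that of Hsp90aa1 from -0.16 to -0.10 and that of Hspa4l from -0.18 to -0.06. Of the replication-dependent histones, 2 reached the filter, too few to test.

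The fold between the groups followed gene composition. Across 10054 protein-coding genes, which are not independent replicates, the log2 fold correlated with GC content (Spearman 0.557, Pearson 0.520) and with log2 gene length (Spearman -0.395, Pearson -0.388). In the decile of lowest GC content the median fold was -0.11, and in the decile of highest GC content 0.09. Per library, the deviation of the log2 value from the mean of the 6 libraries was fitted on GC content and log2 length together. Such slopes compare libraries with each other and do not show how expression itself runs with GC content or length. The slope on GC content was -0.050, -0.0041 and -0.078 per 10% in Control 2, 3 and 4 and 0.095, -0.0067 and 0.044 in SMF 1, 2 and 3 (exact permutation p = 0.2, two-sided). The slope on each doubling of length was 0.0119, 0.0156 and 0.019 in the controls and -0.0274, 0.0044 and -0.0235 in the SMF libraries (exact permutation p = 0.1, the smallest that 3 against 3 allows).

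**Figure D3:**
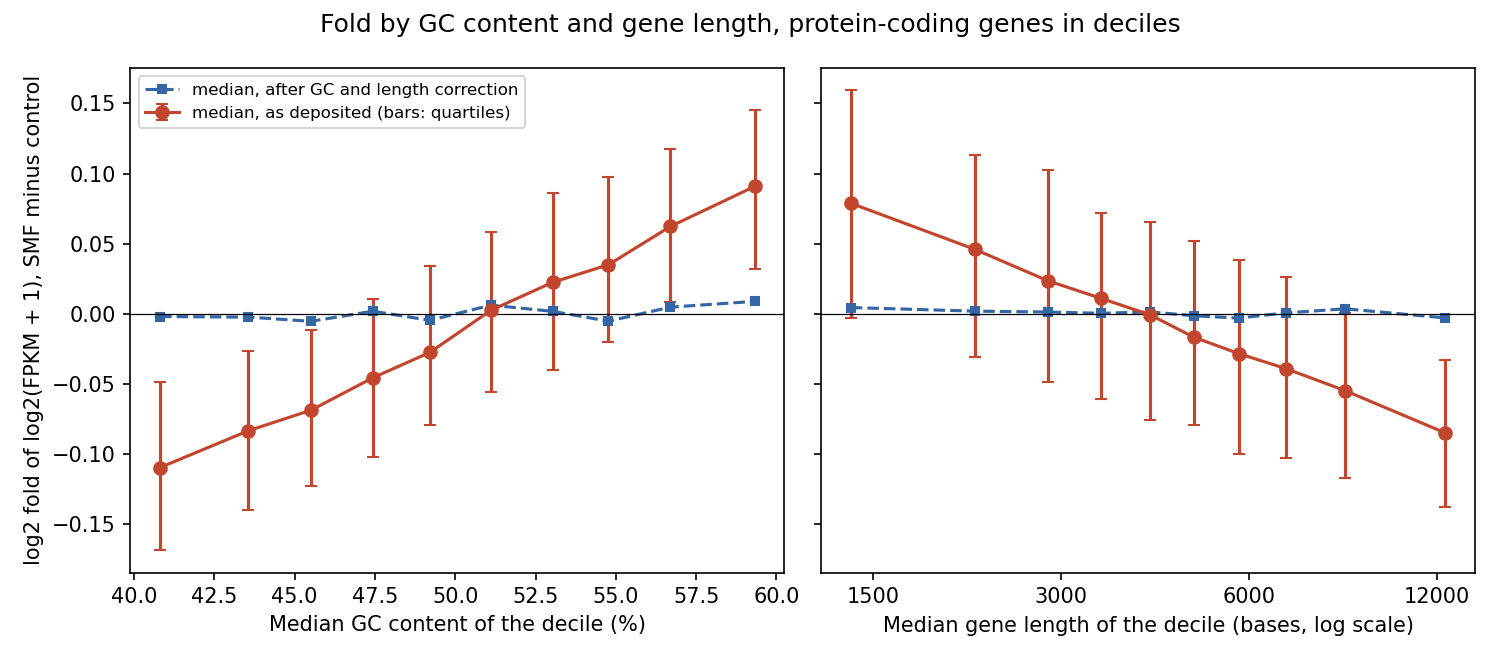
Median log2 fold of log2(FPKM + 1), SMF minus control, in deciles of GC content (percent, left) and gene length (bases, log scale, right), for protein-coding genes. Bars span the quartiles; the median runs from -0.11 to 0.09 over GC content as deposited, and lies near 0 after the correction.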

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

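limma-voom on recovered reads, its variants and the corrections with a library left out were chosen after seeing the data. The count of 0 genes in each direction by limma on log2(FPKM + 1) stayed at 0 under both pseudocounts, no filter, 3 other scalings, no variance trend, the GC content and length correction, a threshold of 0.01 and a minimum fold of 1.5. With a filter at 5 FPKM, 6 genes were higher and 2 lower, Ndufa12 and Gstp1 among them, with 7482 genes tested in place of 11114. Leaving out 1 library gave 0 to 2 higher and 0 to 1 lower. limma-voom called 238 higher and 259 lower, and, higher and lower, 107 and 103 without Control 2, 188 and 262 without Control 3, 4 and 4 without Control 4, 37 and 22 without SMF 1, 593 and 853 without SMF 2, and 51 and 26 without SMF 3. With the correction it called 52 higher and 24 lower. The list counts of 7 higher and 4 lower ranged from 6 to 7 higher and 2 to 5 lower when 1 library was left out, with 2 lower without SMF 2, since hypoxia and cholesterol synthesis lost their calls. With an estimated correlation and with the directional test of fry, 0 were higher and 0 lower; the estimated correlation takes the place of the preset 0.01, while fry asks another question, whether a list's genes move on balance one way, without comparing them with other genes. limma-voom values with the correction gave 7 lists lower, and the correction with 1 library left out gave 6 to 8 higher and 2 to 7 lower. Otherwise the cause of these moves was not tested. The immediate early genes, not called as deposited, turned lower after the correction, with medians of -0.072 (limma), -0.082 (limma-voom), and -0.071, -0.052, -0.061 and -0.068 without Control 3, Control 4, SMF 2 and SMF 3. Among the other list results, 43 gained a call in a setting, 36 lost one and 778 did neither. Changes of sign in genes or lists called in neither setting came to 266, and those of lists lie within the 778. Under the 3 other scalings the median log2 fold of all tested genes lay within 0.0395 of 0. The farthest was -0.0395 under TPM, over its 13131 genes, against -0.00955 as deposited over 11114.

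The groups share the replicate numbers 2 and 3 only, and no label ties a number to a day or batch. Deviations from the group means correlated across genes by 0.058 for the pair numbered 2 and 0.046 for the pair numbered 3, so the numbers were not taken to pair the samples. With the replicate block, on 4 libraries and 1 residual degree of freedom, 13 genes were higher and 6 lower, and 7 lists were higher and 7 lower, superoxide removal losing its call.

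In simulated data limma on log2(FPKM + 1) recovered 40% of genes changed 1.2-fold, and the genes called by limma-voom here had a median absolute log2 fold of 0.24, so a count of 0 does not show that genes were alike. Depth limits low genes, such as Snord71 with a mean of 2.83 reads.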

Other observations

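The planned fits used in this part were limma on log2(FPKM + 1), its GC content and length correction, the other scalings and the fixed lists. Other tests, and the use of any fit to weigh an explanation, were chosen after the results they bear on had been seen. Among the 76 genes that limma-voom called with the GC content and length correction were Plin2 and Scd2, named by rule, and Crip1, Irs2 and Tjp1, picked here after their values were seen. Plin2, which coats lipid droplets, was at 113.9 ± 3.17 FPKM in controls and 130.3 ± 5.66 in SMF libraries (adjusted p = 0.0149). Crip1, a LIM-domain protein, was at 148.8 ± 7.56 and 186.8 ± 16.7 FPKM (adjusted p = 0.00692). Lower were Irs2, an adaptor of the insulin receptor, at 14.6 ± 0.69 and 12.3 ± 0.43 FPKM (adjusted p = 0.00961), Scd2, a fatty acid desaturase, at 692.7 ± 24.9 and 612.8 ± 33.0 (adjusted p = 0.0178), and Tjp1, a tight junction protein, at 31.55 ± 1.147 and 26.3 ± 2.48 (adjusted p = 0.0373). None of these 5 passed limma on log2(FPKM + 1).

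Some lists not called as deposited were called by camera once the GC content and length trend was removed from each library. Fatty acid oxidation and PPARA targets (corrected median 0.043, adjusted p = 0.0287) and the unfolded protein response (0.048, adjusted p = 0.0287) were higher. Ribosome biogenesis (-0.057, adjusted p = 0.0183) and TGF-beta targets and extracellular matrix (-0.043, adjusted p = 0.0305) were lower. These 4 calls used the preset correlation. On values as deposited, camera with an estimated correlation gave adjusted p = 0.516 to 0.773 for these lists. None of these 4 calls held with every library left out: fatty acid oxidation was lost without Control 4 (median 0.037, adjusted p = 0.129) or SMF 1 (0.045, 0.075), and the unfolded protein response without Control 2 (0.047, 0.116) or SMF 2 (0.031, 0.124). Ribosome biogenesis was lost without Control 2 (-0.051, 0.0658) or SMF 3 (-0.025, 0.235). TGF-beta targets were lost without Control 2 (-0.04, 0.199), Control 4 (-0.037, 0.0504), SMF 1 (-0.031, 0.0642) or SMF 3 (-0.05, 0.0609). Cytoplasmic ribosomal proteins and the genes that assemble ribosomes lay on opposite sides of 0 after the correction, a difference that was not itself tested. Hif1a itself was at 14.5 ± 0.70 FPKM in controls and 11.9 ± 1.32 in SMF libraries (limma-voom adjusted p = 0.0173, 0.173 after the correction).

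The respiratory chain and ribosomal protein lists hold short genes (median lengths of 1643.5 to 2015 bases) with a median GC content of 49.39 to 52.14%, near the middle of all genes, so a trend in GC content and length is a candidate explanation. Against the trend as the whole of it, lists matched on GC content, length and level had medians centred on 0.038 to 0.054, below those of these 3 lists. All 3 kept their calls by camera with the preset correlation after the correction, also with any 1 library left out. Their medians lay at or above the 99.99 percentile of the 10000 matched lists, whose genes were drawn independently. That rank leaves out the co-variation of real members and does not measure chance. The corrected medians were 0.07 to 0.10 in place of 0.11 to 0.14, so the trend may account for part of the size. Another scaling left every call but lowered the ribosomal median to 0.046 under quantile normalization, so a share from scaling stays open. After the correction SMF 2 lay within the control range, and the grouping that exchanges Control 3 and SMF 2 gave a smallest absolute median of 0.0709 over the 3 lists, as large as the 0.0705 of the real grouping, so an effect of the field stays open and untested.

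The splicing and nuclear speckle list may owe its fall to the same trend. Its median went from -0.10 (SD over members 0.0911) to -0.0115 (SD 0.0909) after the correction, and the call ended because the median shrank while the spread did not. Among matched lists its median stood at the 3.85 percentile. Neat1 kept its own limma-voom call after the correction. Whether the trend goes with the field cannot be told apart from variation between libraries, since 3 against 3 cannot give an exact permutation p under 0.1 and the p of 0.2 for the GC slope decides nothing; SMF 2 lay among the controls in GC slope, while every SMF library lay below every control in length slope.

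Gstp1 was lower in 3 of 3 SMF libraries, which the naming rule required. Reads moved to its listed relatives would leave the family sum level, but the summed reads, scaled to library totals, of Gstp1, Gstp2, Gstp3 and Gstp-ps differed by -0.553 on the log2 scale, with 76.1 to 85.8 in controls and 49.5 to 61.0 in SMF libraries. The trend in GC content and length argued the other way, since the fold went from -0.557 (SE 0.0769) to -0.648 (SE 0.0732) after the correction. Reads discarded for mapping to unlisted copies were not tested, and the field stays open as a hypothesis.

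The 6 libraries can be parted 3 against 3 in 10 ways, too few for a share under 0.05. For limma on log2(FPKM + 1), the real split gave 0 genes and the highest other 1, so all 10 gave as many. At an unadjusted p below 0.05 the real split gave 1998 genes and the highest other 1273, with 1 of the splits as large, the real one. For lists called by camera, the real split gave 11 and another also 11, that of Control 2, SMF 1 and SMF 3 against the rest, so 2 of the splits gave as many. limma-voom called 497 genes in the real split and 0 in each other; after the correction it called 76 against at most 2, and camera called 14 lists against at most 9, each with 1 split as large. The corrected medians of the respiratory chain and ribosomal lists did not set the real split apart in this way, since Control 2, Control 4 and SMF 2 against the rest gave as large a shift.

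Of the 11 called lists, 5 had medians above the middle 95% of their matched lists and 3 below it, while ATF4 targets, superoxide removal and the splicing list lay inside it. Autophagy stood at the 99.95 percentile, NF-kB genes at 100, cholesterol synthesis at 0.26, and mitosis and hypoxia at 0. These ranks leave out the co-variation of list members, and hypoxia stood at 0 although its groups overlapped.

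The lists with hypoxia and glycolysis genes varied most within groups. The glycolysis score had an SD of 0.0943 over controls and 0.104 over SMF libraries, and the hypoxia score 0.146 and 0.122.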
